A study of Mus musculus with 45 samples.

How the data were processed

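Epithelial cells were sorted from small intestines of mouse embryos of a mixed C57BL/6 and CD1 background as EpCAM-positive cells, 500 per library, and each replicate came from a pool of 3 embryos at E13.5 or from 1 embryo at E15.5, per the labels' protocols. Polyadenylated RNA was converted to cDNA with the SMARTer v3 chemistry, amplified for 15 cycles, sheared and made into libraries with the Ovation Ultralow system, per the labels' protocols. The authors deposited 1 table of whole-number read counts per gene for each of the 45 libraries. Demultiplexing with bcl2fastq 1.8.4, alignment with STAR 2.3.1z13, SAMtools 1.2, counting with HTSeq 0.6.1p1 and DESeq2 1.14.1 are named per the submitters' processing notes, with mouse build mm9. The gene annotation and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes cannot be separated. Reads that align to more than 1 place were not assigned to genes, which makes levels of closely related genes, such as the globins, the Hox and Ifitm families and Clca3, uncertain. The reads carry no molecular identifiers, so after PCR a count of reads is not a count of molecules.

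Each deposited table closed with 5 lines that name no gene (reads without a feature, ambiguous reads and the like). They were left out of library sizes and tests, and held 23.9 to 29.4% of the reads in the Axin2 cohort and 33.4 to 49% in the Id2 cohort. Library totals over genes ran from 16521311 to 37729425. Genes with at least 1 read numbered 13109 to 17387 per library. Replicates of a group were compared by a chi-square test of their counts, which gave 14.9 to 357 per degree of freedom. None was a copy of another. Per the series' design text the replicates are biological, being pools of embryos at E13.5 and single embryos at E15.5. The main fit described below shares 1 estimate of the spread per gene over all groups. Its p-values therefore do not describe the spread of 1 stage or cohort alone, and fits with only the libraries of the same setting are given beside it.

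Groups were taken from the sample titles as marker line, stage, gut part and sorted population. Counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust, TMM normalization) with all 45 libraries in one fit of 15 group means, which leaves 30 residual degrees of freedom. Genes were kept by filterByExpr (minimum count 10, minimum total 15), 15513 of 23366. P-values were adjusted by the Benjamini-Hochberg method and genes with adjusted p below 0.05 were called. A log2 CPM used a prior count of 2. The 15 contrasts cover stage and gut part (each averaged over the 3 populations present on both sides), Lgr5-positive against Lgr5-negative unlabelled cells in 4 settings, labelled against unlabelled Lgr5-positive cells in 3 settings, labelled cells of unstated Lgr5 state against Lgr5-negative unlabelled cells in 4 settings, and 2 differences of differences. Contrasts, the gene and list tests, gene lists and the rule for named genes were fixed before the data were examined.

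Gene lists for 29 cell types, pathways, gut regions and other tissues were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. Of 583 list genes 576 were matched to the files. Of 107 list calls over all contrasts, 15 held with an estimated correlation and 35 with fry, and every list call not described was lost with an estimated correlation. Named genes are Lgr5, Axin2, Id2 and Epcam in every contrast; then, among genes with adjusted p below 0.05, an average log2 CPM of at least 3, no overlap between the libraries of the 2 sides (within each population for the averaged contrasts, not asked of differences of differences) and a proper symbol, the 10 with the largest fold change in each direction; then up to 4 members with the smallest adjusted p of each list called or discussed. Some genes that this rule names are not reported here.

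The groups share replicate numbers in the sample titles, but the labels do not say what a number marks. Whether numbers pair the libraries was checked on 9289 genes with log2 CPM of at least 3, as the correlation of same-numbered libraries' deviations from their group means, and a contrast was taken as paired where all 3 correlations exceeded 0.1. That held for the Lgr5 contrast at E13.5 in the Axin2 cohort (0.236 to 0.727) and the Id2 cohort (0.28 to 0.499), for labelled against unlabelled Lgr5-positive cells in the posterior part (0.1 to 0.566) and the Id2 cohort (0.17 to 0.566), and for labelled against Lgr5-negative cells in the anterior part (0.403 to 0.72) and the Id2 cohort (0.128 to 0.528). Between the gut parts it held in labelled cells (0.335 to 0.408) but not in the 2 unlabelled populations. The pairing is therefore read from the data and not from the labels.

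Alternatives were DESeq2 1.42.0, limma 3.58.1 (voom with library quality weights), RLE size factors, no filter on low counts, a minimum fold of 2, only the libraries of the same setting, the replicate number as a block, all libraries thinned to 16521311 reads, sex-linked genes left out, and each library left out in turn. Chosen after seeing the data were a fit without 3 libraries that stood apart (posterior Lgr5-positive unlabelled replicate 3, posterior Lgr5-negative unlabelled replicate 2 and E13.5 Axin2 Lgr5-positive labelled replicate 1) and one with each library's trend over transcript length removed (lowess, span 0.3, 9755 genes). Transcript lengths came from a GRCm38 annotation used only for lengths and names, since its build differs from that of the files; 15380 of the 15513 genes (99.1%) were matched. A library's position score is the mean log2 CPM of genes called higher in the posterior part minus that of genes called lower, sex-linked genes left out, and its stage score the same for E15.5 against E13.5. The scored libraries of those contrasts also entered the choice of genes. Scores and permutation tests were made in R with seed 1, and transcript lengths and figures in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9).

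The edgeR gene test and camera were tried on simulated data with 200 genes changed, for the contrasts given here only. Each gene was drawn independently for every library at its mean over all libraries. The simulated data thus held no cohort differences, outlying libraries or pairing, and the shares below hold for such data. Other contrasts and steps were not tried in this way. For the stage contrast (15213 genes) 68% of genes changed 2-fold and 90% of those changed 4-fold were recovered, for the gut part contrast (15171 genes) 65% and 85%, for the Lgr5 contrast at E13.5 31% and 62% in the Axin2 cohort (15183 genes) and 24% and 64% in the Id2 cohort (15199 genes), and for the difference of differences between stages (15219 genes) 12% and 48%. Genes left unchanged in the simulation made up 4.8%, 2%, 2.1%, 2.2% and 11.8% of the calls in the same order.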

Results

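RNA was sequenced from epithelial cells of the mouse embryonic small intestine, sorted on EpCAM, a surface adhesion protein of epithelia, at 500 cells per library. A tdTomato lineage label had been started at embryonic day 9.5 in cells expressing either Axin2, a Wnt target gene, or Id2, an inhibitor of basic helix-loop-helix factors. Cells were collected at E13.5 or E15.5. Lgr5, the receptor that marks adult intestinal stem cells, gave a second sorting criterion. Unlabelled cells were taken as Lgr5-positive and Lgr5-negative, labelled cells as Lgr5-positive, and a further labelled population was named without its Lgr5 state, which the labels do not give. The Axin2 cohort held E13.5 gut and the anterior and posterior parts at E15.5, and the Id2 cohort held E13.5 gut alone. Lgr5-positive labelled cells of the anterior part were not analysed here. The 45 libraries formed 15 groups of 3, each replicate being a pool of 3 embryos at E13.5 and 1 embryo at E15.5. Reads assigned to genes ranged from 16521311 to 19702205 per library in the Axin2 cohort and from 26888154 to 37729425 in the Id2 cohort. Levels are given as CPM (counts scaled to library size), mean ± SD, with n = 3 unless another n is stated, and fold changes as fitted log2 values ± standard error.

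The level of Lgr5 itself was compared between the sorted populations first, as a check of the sort. In the E13.5 Axin2 cohort Lgr5 stood at 4.53 ± 3.28 CPM in Lgr5-negative unlabelled cells, 16.4 ± 12.4 in the labelled cells of unstated Lgr5 state, 73.1 ± 39.3 in Lgr5-positive unlabelled cells and 110 ± 60.8 in Lgr5-positive labelled cells. The Id2 cohort had 29.5 ± 19, 17.1 ± 14.6, 71.8 ± 9.61 and 145 ± 90.1 CPM in the same order. At E15.5 the anterior part gave 8.53 ± 3.93, 39.7 ± 36.9 and 46.6 ± 20.3 CPM in Lgr5-negative, labelled and Lgr5-positive unlabelled cells, and the posterior part 10.2 ± 5.95, 27.5 ± 1.74 and 55.7 ± 21.8, with 58.3 ± 22 in Lgr5-positive labelled cells. Within E13.5 of the Axin2 cohort the excess of Lgr5 in Lgr5-positive unlabelled cells passed the test at a log2 fold change of 4.02 ± 0.83 (adjusted p = 0.00687), though not without Lgr5-negative replicate 2 (adjusted p = 0.0662). It missed the threshold in the Id2 cohort (1.28 ± 0.74, adjusted p = 0.544) and in the anterior (2.45 ± 0.78, adjusted p = 1) and posterior parts (2.45 ± 0.78, adjusted p = 0.151). Whether the Lgr5 excess itself differed between the cohorts was not tested, and between the stages its difference was -1.57 ± 0.92 (adjusted p = 1). Axin2 remained low throughout the E13.5 Axin2 cohort, between 2.14 ± 1.2 CPM in Lgr5-negative unlabelled and 5.03 ± 1.06 CPM in Lgr5-positive labelled cells. Epcam was abundant in every group, with group means from 1880 to 3140 CPM.

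**Figure D1:**
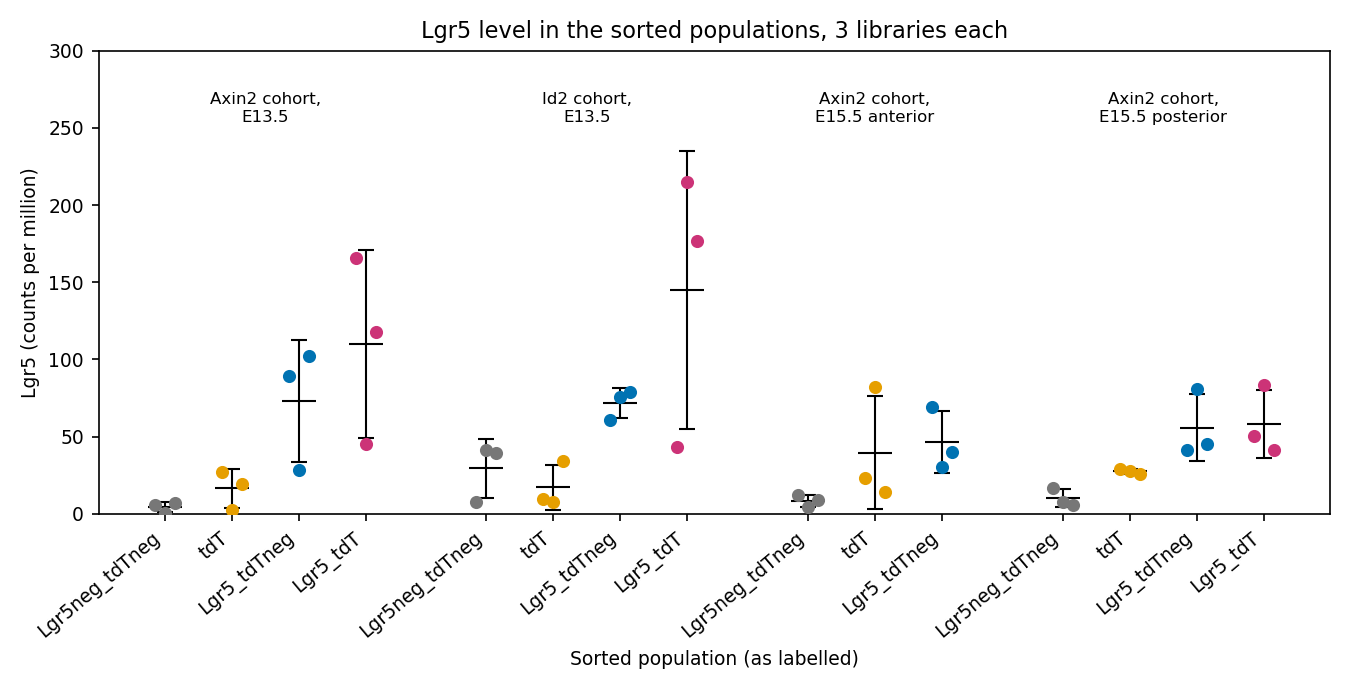
Lgr5 in CPM on the y axis for the sorted populations on the x axis, with 3 libraries per group as points and the mean with its SD as a bar and error bar. Means in Lgr5-positive groups range from 46.6 to 145 CPM, and in Lgr5-negative unlabelled groups from 4.53 to 29.5 CPM.

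The Id2 and Axin2 cohorts were set side by side to see how far libraries from the 2 lines could be compared directly. Principal component 1 carried 46.3% of the variance and parted the cohorts, and component 2 with 14.7% parted E13.5 from E15.5 within the Axin2 cohort (lowest 10.5 against highest 7.4). The E13.5 libraries of the Id2 cohort lay from -19.3 to 12.3 on component 2 and overlapped those of E15.5. Between the Lgr5-negative unlabelled groups of E13.5, 2320 genes were higher and 2173 lower in the Id2 cohort. The Id2 gene was at 1880 ± 456 CPM there against 1040 ± 317 CPM in the Axin2 cohort. Marker line, sequencing depth and any processing difference between the cohorts cannot be told apart, so labelled cells were compared only with unlabelled cells of their own cohort.

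**Figure D2:**
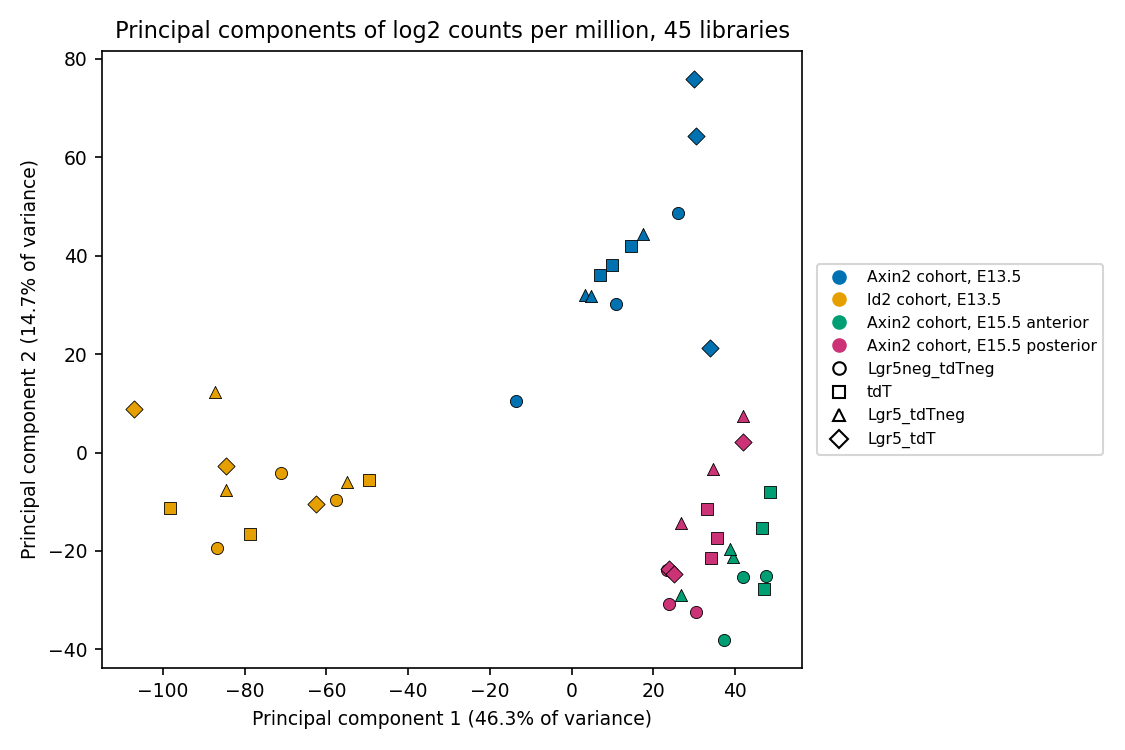
Principal component 1 (x axis, 46.3% of variance) and 2 (y axis, 14.7% of variance) of log2 CPM in the 45 libraries, colored by cohort, stage and gut part and shaped by sorted population. Component 1 separates the 12 Id2 libraries from the 33 Axin2 libraries.

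How the epithelium changed from E13.5 to E15.5 was asked over the 3 populations present at both stages in the Axin2 cohort (18 libraries against 9). Libraries were taken as independent, although gates and parts of 1 number may share an embryo or pool. The SDs, standard errors and p-values of this comparison may therefore not describe the spread between embryos. Genes of secretory lineages rose from near the floor. Tff3, a goblet cell trefoil peptide, reached 328 ± 158 CPM (n = 18) from 6.28 ± 3.63 CPM (n = 9), a log2 fold change of 5.88 ± 0.45 (adjusted p = 1.43e-12), and Agr2, a disulfide isomerase needed for mucin production, rose by 5.70 ± 0.46. Neurod1, a transcription factor of enteroendocrine cells, rose to 46.5 ± 34.7 CPM, and Chgb, a protein of their secretory granules, to 268 ± 227 from 0.69 ± 0.394 CPM (log2 fold change 8.39 ± 0.87). Mttp, which loads lipid onto lipoprotein particles in absorptive cells, rose by 3.29 ± 0.22, and the transmembrane mucin Muc13 rose to 481 ± 76 from 86.3 ± 21.9 CPM. The strongest falls included Pth1r, the parathyroid hormone receptor, at 2.46 ± 1.95 against 249 ± 49.5 CPM (log2 fold change -6.96 ± 0.37), and Ltbp1, which binds latent TGF-beta, at -5.39 ± 0.46. Id2 itself fell by 1.07 on the log2 scale (SE 0.10, adjusted p = 1.23e-10), from 1030 ± 192 to 500 ± 122 CPM, and Epcam changed by 0.33 ± 0.09, while Lgr5 (0.51 ± 0.38, adjusted p = 0.327) and Axin2 (0.62 ± 0.31, adjusted p = 0.118) did not pass. In all, 2425 genes were higher and 2779 lower at E15.5 (edgeR's quasi-likelihood test), against 4117 and 4842 with voom and 2641 and 2513 with RLE size factors. Taken one at a time, the labelled population gave 843 higher and 1083 lower genes, Lgr5-positive unlabelled cells 726 and 748, and Lgr5-negative unlabelled cells 886 and 1177.

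Gene lists fixed beforehand followed these genes. Of 21 goblet and Paneth cell genes, 17 rose and 0 fell (19 and 0 adjusted over the list alone; camera adjusted p = 1.08e-18, and adjusted p = 0.00387 with an estimated correlation). Among 41 enterocyte genes 30 rose and 1 fell (30 and 1 adjusted over the list alone), with Cdhr5, a brush border protocadherin, at 1.42 ± 0.10 (camera adjusted p = 9.09e-18; adjusted p = 0.0022 with an estimated correlation). Enteroendocrine genes numbered 24 higher and 2 lower of 33, unchanged when adjusted over the list alone, with the hormone gene Sct at 280 ± 139 CPM against 10.8 ± 1.45 (camera adjusted p = 2.75e-12). The list test was lost at adjusted p = 0.053 with an estimated correlation. In the opposite direction, 12 of 18 fetal progenitor genes fell and 1 rose (12 and 1 adjusted over the list alone; camera adjusted p = 6.55e-06; adjusted p = 0.000295 with an estimated correlation). Bex1 went from 540 ± 174 to 188 ± 82.9 CPM (-1.59 ± 0.09). Hmga2, a chromatin protein of embryonic cells, changed by -1.30 ± 0.14, and the basement membrane collagen Col4a1 by -2.60 ± 0.30. YAP targets comprised 11 lower and 4 higher of 18 (12 and 4 adjusted over the list alone; camera adjusted p = 0.00186; adjusted p = 0.132 with an estimated correlation). Among them Ajuba was at -2.08 ± 0.21. Of 11 Hedgehog pathway genes 5 fell and 0 rose (6 and 0 adjusted over the list alone), among them the transcription factor Gli3 (-3.07 ± 0.33) and the ligand Shh (-1.86 ± 0.25), with camera adjusted p = 0.0223 and adjusted p = 0.216 with an estimated correlation. The intestinal stem cell list moved both ways, 8 genes up and 5 down of 24 (8 and 7 adjusted over the list alone; camera adjusted p = 0.973). Smoc2 rose by 2.28 ± 0.32, with Fstl1, which the YAP list also holds, at -3.54 ± 0.18. The calls of every gene named for this comparison held when each library was left out in turn.

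**Figure D3:**
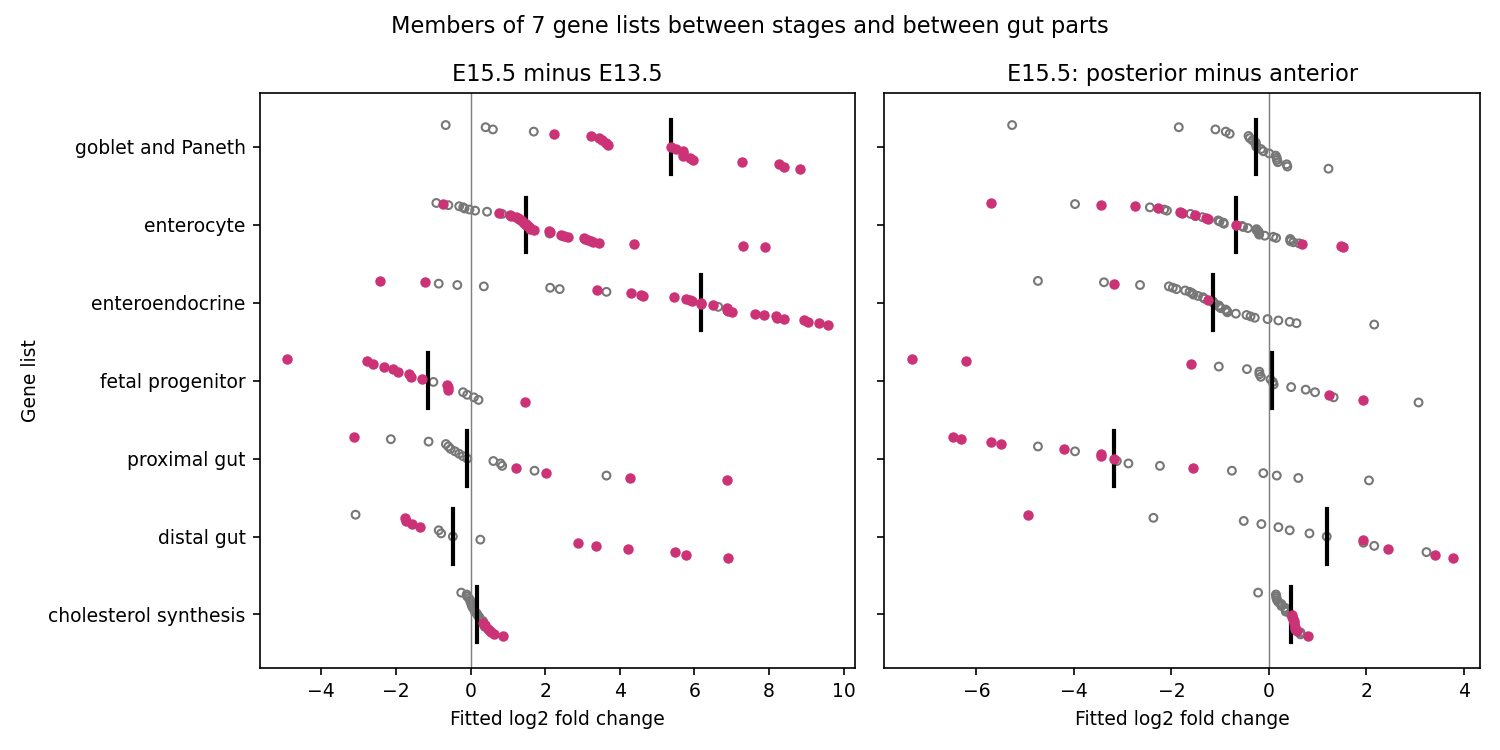
Fitted log2 fold change on the x axis for the measured members of 7 gene lists on the y axis, between stages (left) and between posterior and anterior parts at E15.5 (right). Filled points are genes with adjusted p below 0.05 and black bars are list medians, 5.37 for goblet and Paneth genes between stages and -3.18 for proximal gut genes between parts.

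Position along the gut was examined at E15.5 by setting the posterior against the anterior part over the same 3 populations (9 libraries each). Here too the libraries were taken as independent, although those of 1 number may share an embryo. Sfrp5, a secreted Wnt antagonist, fell from 224 ± 85.4 CPM in the anterior to 0.624 ± 0.434 CPM in the posterior part, a log2 fold change of -8.46 ± 0.56 (adjusted p = 1.41e-12). Onecut2, a duodenal transcription factor, was at 1.77 ± 1.71 against 63.3 ± 23 CPM, Fabp1, a fatty acid carrier of the proximal intestine, at 2.66 ± 1.88 against 127 ± 66.7, and the alcohol dehydrogenase Adh1 at 12.8 ± 4.27 against 143 ± 98.1. In the posterior part the Wnt receptor gene Fzd10 was higher at 10.7 ± 5.27 against 0.9 ± 0.626 CPM (log2 fold change 3.64 ± 0.44, adjusted p = 4.88e-07). So were Osr2 (1.94 ± 0.21) and the scaffold protein Lin7a (4.87 ± 0.46). Id2 was also higher there, at 596 ± 88.6 against 404 ± 55.8 CPM (0.56 ± 0.12, adjusted p = 0.00335), while Lgr5 was at -0.01 ± 0.43 (adjusted p = 1). The test called 289 genes higher and 276 lower in the posterior part, against 825 and 928 with only the E15.5 libraries and 1068 and 1548 with voom. By population the numbers were 30 and 12 in labelled cells, 40 and 36 in Lgr5-positive and 32 and 19 in Lgr5-negative unlabelled cells.

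Of 19 proximal gut genes 9 were lower and 0 higher in the posterior part (14 and 0 adjusted over the list alone; camera adjusted p = 6.41e-17; adjusted p = 0.000255 with an estimated correlation). Of 15 distal gut genes 4 were higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 1.45e-05; adjusted p = 0.0204 with an estimated correlation). Cholesterol synthesis genes were higher posteriorly, 9 of 24 with 0 lower (15 and 0 adjusted over the list alone; camera adjusted p = 4.13e-14; adjusted p = 0.000322 with an estimated correlation). Sc4mol, the sterol methyl oxidase, stood at 688 ± 179 against 387 ± 80.7 CPM (0.80 ± 0.14), and the lanosterol demethylase Cyp51 rose by 0.53 ± 0.12. Enterocyte genes showed 10 lower and 3 higher of 41 (15 and 4 adjusted over the list alone; camera adjusted p = 7.7e-08; adjusted p = 0.0525 with an estimated correlation). Rbp2, a retinol carrier, was at -3.44 ± 0.57 and Mttp at -1.51 ± 0.21. Glycolysis genes had 3 higher and 0 lower of 15 (6 and 0 adjusted over the list alone; camera adjusted p = 0.00025; adjusted p = 0.0669 with an estimated correlation), including lactate dehydrogenase Ldha at 0.37 ± 0.09. The liver and pancreas list had 8 of 14 genes lower and 1 higher (9 and 2 adjusted over the list alone; camera adjusted p = 0.00135; adjusted p = 0.315 with an estimated correlation). That list call was lost without anterior Lgr5-positive replicate 2 (adjusted p = 0.169). Calls of the genes named for this comparison held with each library left out.

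Whether Lgr5-positive cells already differed from Lgr5-negative cells at E13.5 was asked in unlabelled cells of both cohorts. In the Axin2 cohort, genes known from adult intestinal stem cells were higher in Lgr5-positive cells. Smoc2, a matricellular protein of those cells, stood at 208 ± 47.2 CPM against 2.9 ± 1.4 (log2 fold change 6.17 ± 0.71, adjusted p = 1.45e-06), and Ascl2, a Wnt-driven transcription factor, at 103 ± 15.4 against 11.3 ± 1.22 (3.18 ± 0.52). Slc12a2, an ion cotransporter of crypt cells, differed by 1.65 ± 0.34, though not without Lgr5-negative replicate 3 (adjusted p = 0.0718). Vav3, a guanine nucleotide exchange factor, rose by 4.49 ± 0.43 and the intestinal homeobox gene Cdx1 by 3.91 ± 0.77. Much lower in Lgr5-positive cells were Sfrp5, at 0.853 ± 0.349 against 481 ± 206 CPM (-9.13 ± 0.96), Gata4, a transcription factor of the proximal gut, at 12.6 ± 10.9 against 202 ± 76.9 (-4.00 ± 0.64), and Onecut2 at -7.11 ± 1.34. Axin2 (0.95 ± 0.60), Id2 (0.06 ± 0.21) and Epcam (-0.36 ± 0.18) did not pass. The test called 68 genes higher and 67 lower. It called 111 and 122 with the replicate number as a block, 110 and 141 with DESeq2 and 1098 and 1206 with voom. The voom library weights were 0.598, 0.821 and 9.54 in Lgr5-negative replicates 1, 2 and 3, so replicate 3 carried most of the weight of its group. Leaving out Lgr5-positive replicate 1, 2 or 3 left 74, 78 or 65 genes, and leaving out Lgr5-negative replicate 3 left 77.

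The Id2 cohort gave 23 genes higher and 51 lower in Lgr5-positive unlabelled cells, 74 in all. It gave 343 with the replicate number as a block, 338 with DESeq2, 17 with voom and 2 with only the libraries of that cohort. The count fell to 22 without Lgr5-positive replicate 2 and to 35 without Lgr5-negative replicate 2. Sord, the sorbitol dehydrogenase, was higher at 69.7 ± 25.3 against 10.8 ± 3.88 CPM (2.70 ± 0.35), Bex1 at 1.08 ± 0.19, and Vav3 at 1.93 ± 0.39 (adjusted p = 0.0105, and 0.0551 without Lgr5-negative replicate 1). Sfrp5 was again lower, at 7.5 ± 5.07 against 187 ± 125 CPM (-4.65 ± 0.77, adjusted p = 0.0018), as was Clps, the pancreatic colipase, at 2.08 ± 0.719 against 319 ± 148 CPM (-7.27 ± 1.08). Summed levels of the liver and pancreas list, which does not hold Clps, were 1180, 5610 and 2870 CPM in the 3 Lgr5-negative libraries. That list had 0 of 14 called and 8 lower adjusted over the list alone (camera adjusted p = 0.00147, and adjusted p = 0.464 with an estimated correlation). Values for Smoc2 (2.08 ± 0.58, adjusted p = 0.0968), Cdx1 (2.50 ± 0.73, adjusted p = 0.115) and Gata4 (-1.65 ± 0.58, adjusted p = 0.231), chosen after their values were seen, missed the threshold. Calls shared by the cohorts, which have no library in common, numbered 12 higher genes (0.101 expected of independent lists) and 21 lower (0.22 expected). Of the 68 higher and 67 lower genes of the Axin2 cohort, 134 had the same sign in the Id2 cohort. Xist, from the inactive X chromosome, was detected without Y-linked reads in Lgr5-positive replicates 2 and 3 of the Id2 cohort, while Lgr5-negative replicates 2 and 3 held both (164 and 258 CPM of Y-linked transcripts).

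**Figure D4:**
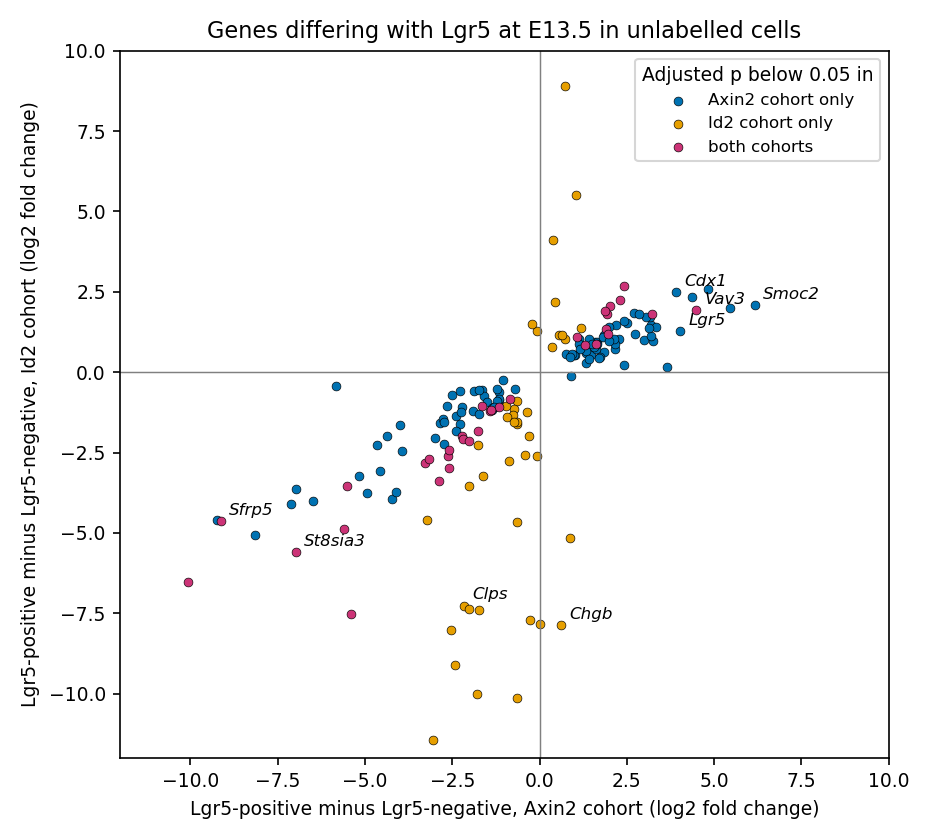
Log2 fold change between Lgr5-positive and Lgr5-negative unlabelled cells at E13.5 in the Axin2 cohort (x axis) and the Id2 cohort (y axis), for genes called in either cohort. Of the 68 higher and 67 lower genes called in the Axin2 cohort, 134 lie on the same side of 0 in both.

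Among the gene lists at E13.5, the intestinal stem cell list was higher in Lgr5-positive cells of the Axin2 cohort, 4 of 24 genes up and 0 down (5 and 0 adjusted over the list alone; camera adjusted p = 7.1e-13; adjusted p = 0.00118 with an estimated correlation). Lgr5, the sorting marker, is among its members. Proximal gut genes were lower, 4 of 19 down and 0 up (4 and 0 adjusted over the list alone; camera adjusted p = 7.04e-09; adjusted p = 0.012 with an estimated correlation). Of 23 Wnt targets, 2 were higher and 0 lower (3 and 0 adjusted over the list alone; camera adjusted p = 0.000116; adjusted p = 0.0593 with an estimated correlation). Proliferation genes had 0 of 36 called in edgeR and 0 adjusted over the list alone, with 33 of 36 positive (camera adjusted p = 2.54e-06; adjusted p = 0.235 with an estimated correlation). The liver and pancreas list was lower, 1 of 14 down and 0 up (2 and 0 adjusted over the list alone, camera adjusted p = 0.00851, and adjusted p = 0.419 with an estimated correlation). In the Id2 cohort proximal gut genes gave 0 calls over all genes and 9 lower adjusted over the list alone (camera adjusted p = 3.26e-07; adjusted p = 0.0635 with an estimated correlation). Enteroendocrine genes there were lower, 4 of 33 with 0 higher (11 and 0 adjusted over the list alone; camera adjusted p = 1.29e-09; adjusted p = 0.145 with an estimated correlation). Scgn, a calcium binding protein, stood at 0.0701 ± 0.0881 against 13.8 ± 12.9 CPM. Of the 68 and 67 genes of the Axin2 cohort, 71 also differed in the same direction between the posterior and anterior parts at E15.5, where 2.46 would be expected of independent lists. Another 4 differed in the opposite direction, and 112 shared the sign.

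**Figure D5:**
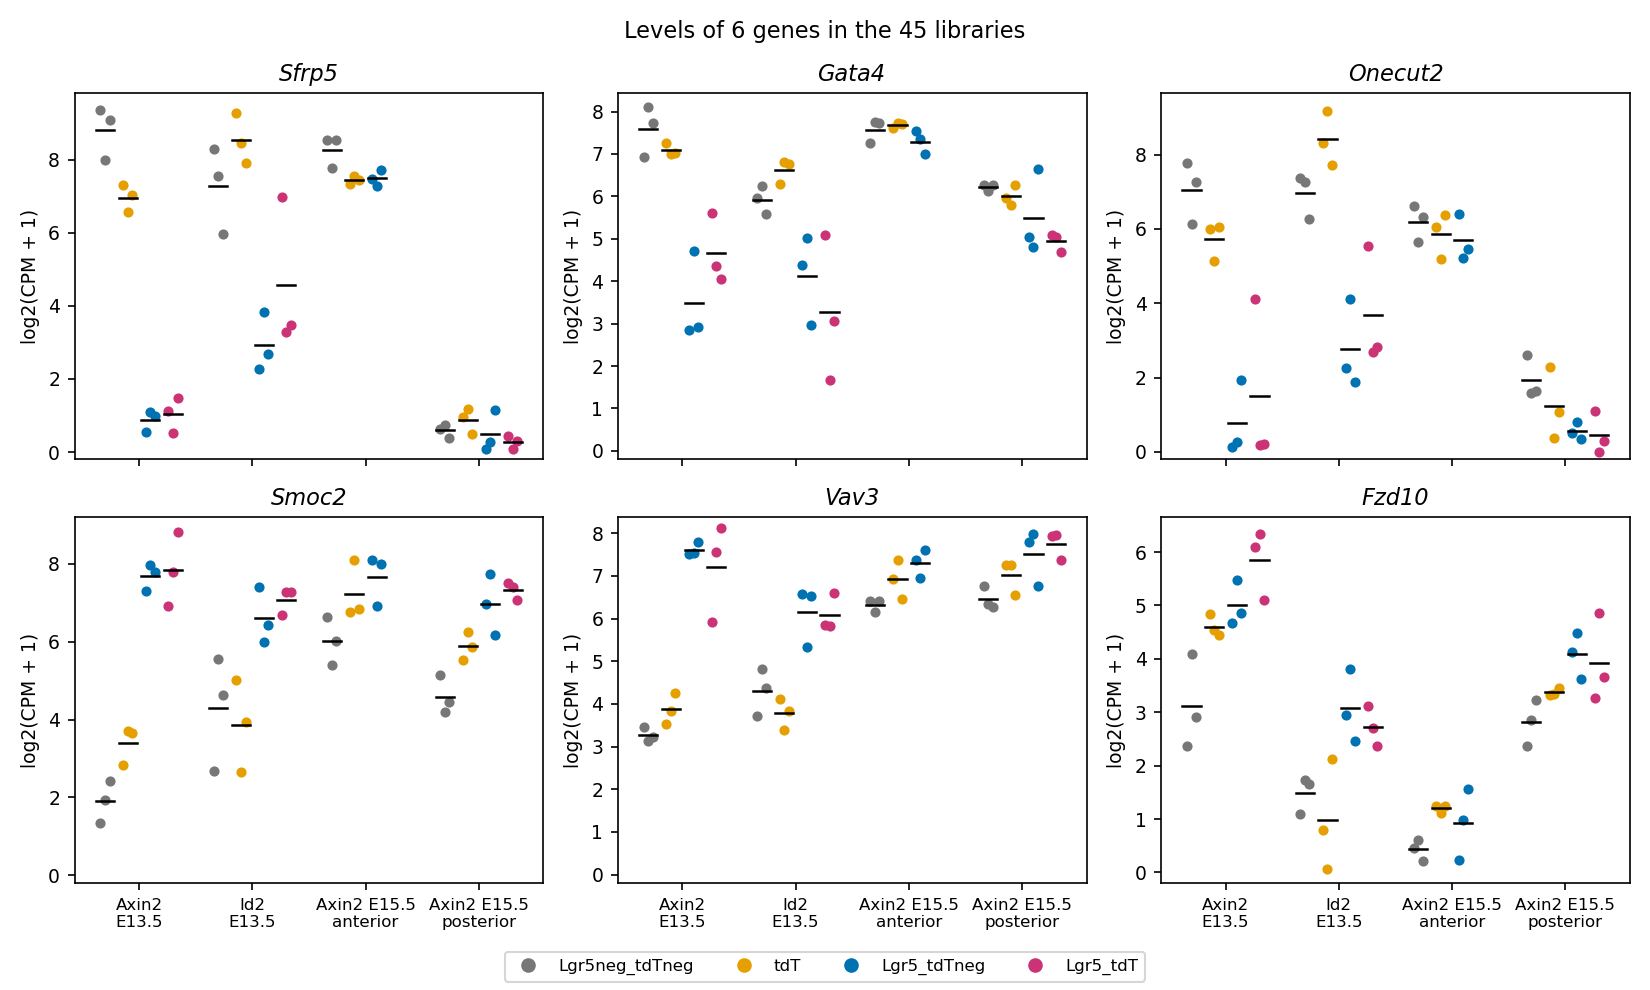
Log2(CPM + 1) of 6 genes on the y axis by cohort, stage and gut part on the x axis, with a point per library colored by sorted population and bars at the mean of 3. Sfrp5 averages 481 CPM in Lgr5-negative and 0.853 CPM in Lgr5-positive unlabelled cells of the E13.5 Axin2 cohort.

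At E15.5 the same contrast of unlabelled cells was made in each gut part, and the difference of the anterior part alone from E13.5 was not tested. Smoc2 averaged 215 ± 82.6 CPM in Lgr5-positive and 68.2 ± 29.1 CPM in Lgr5-negative cells and Vav3 160 ± 35.9 and 79.2 ± 7.94 CPM, genes chosen after their values were seen. There edgeR called 0 genes, with 207 at unadjusted p below 0.05 (776 expected by chance), 42 called by DESeq2 and 1 by limma's voom with library weights. As the edgeR p-values ran higher than chance gives, 0 calls do not show that the gates were alike. Without Lgr5-positive replicate 1, 1 gene was called. As a list, intestinal stem cell genes ranked above other genes, 23 of 24 positive (0 called, 4 higher adjusted over the list alone; camera adjusted p = 6.53e-17; adjusted p = 0.000162 with an estimated correlation). Wnt targets did too, 20 of 23 positive (0 called, 0 adjusted over the list alone; camera adjusted p = 8.88e-11; adjusted p = 0.000728 with an estimated correlation). Enterocyte genes ranked below, 33 of 41 negative (0 called, 0 adjusted over the list alone; camera adjusted p = 4.19e-10; adjusted p = 0.0229 with an estimated correlation). Among lists of other cell types, mesenchyme genes ranked higher, 19 of 22 positive (0 called, 1 adjusted over the list alone, camera adjusted p = 0.000347, and adjusted p = 0.5 with an estimated correlation). The liver and pancreas list ranked lower, 11 of 14 negative (0 called, 0 adjusted over the list alone, camera adjusted p = 0.0307, and adjusted p = 0.516 with an estimated correlation). Haematopoietic genes ranked lower too, 11 of 14 negative (0 called, 0 adjusted over the list alone, camera adjusted p = 0.0177, and adjusted p = 0.45 with an estimated correlation).

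In the posterior part Kit, the receptor of stem cell factor, was higher in Lgr5-positive cells at 73 ± 25 against 8.88 ± 3.31 CPM (3.04 ± 0.48, adjusted p = 0.00106). Also higher were the retinoid carrier Crabp2 at 102 ± 88.3 against 0.226 ± 0.074 (8.79 ± 1.42) and the interferon-inducible membrane protein gene Ifitm3 at 4.57 ± 0.74. Smoc2 was at 136 ± 72.5 against 24.1 ± 8.99 CPM (2.50 ± 0.59, adjusted p = 0.0478) and lost its call without any 1 of the 6 libraries (adjusted p from 0.0709 to 0.393). Wnt targets ranked higher, 22 of 23 positive (0 called, 3 higher adjusted over the list alone; camera adjusted p = 1.71e-06; adjusted p = 0.0185 with an estimated correlation). Cholesterol synthesis genes ranked lower, 1 of 24 called down, Sc5d at 114 ± 13.2 against 231 ± 50.2 CPM (lost without any library but Lgr5-negative replicate 1, at adjusted p from 0.0956 to 0.274; 8 lower adjusted over the list alone; camera adjusted p = 2.1e-07; adjusted p = 0.0185 with an estimated correlation). The stem cell list had 1 gene higher (5 adjusted over the list alone; camera adjusted p = 3.55e-05; adjusted p = 0.0826 with an estimated correlation). The enteroendocrine list had 1 higher and 33 of 33 positive (8 adjusted over the list alone; camera adjusted p = 1.88e-08; adjusted p = 0.0896 with an estimated correlation). Erythroid genes moved with the same gate, 3 of 9 higher (4 adjusted over the list alone; camera adjusted p = 0.000227; adjusted p = 0.0896 with an estimated correlation). Their summed level was 1820, 7.1 and 1590 CPM in the 3 Lgr5-positive libraries, the embryonic globin Hbb-bh1 at 815, 0.812 and 696 CPM. The summed posterior Hox genes followed the same libraries at 72.2, 19.5 and 66.6 CPM. So did the mesenchymal genes Acta2 (37.7, 5.94 and 32.8 CPM) and Lum (19.1, 1.93 and 23.9 CPM), chosen after their values were seen.

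Further lists ranked higher in that gate of the posterior part. Mesenchyme genes were positive for 21 of 22 (0 called, 0 adjusted over the list alone; camera adjusted p = 0.000664, and adjusted p = 0.418 with an estimated correlation) and enteric neuron and glia genes for 14 of 15 (0 called, 0 adjusted over the list alone; camera adjusted p = 0.0149, and adjusted p = 0.451 with an estimated correlation). Posterior Hox genes gave 13 of 14 positive (0 called, 9 adjusted over the list alone, camera adjusted p = 3.5e-05, and adjusted p = 0.165 with an estimated correlation) and anterior Hox genes 15 of 15 (0 called, 5 adjusted over the list alone, camera adjusted p = 3.55e-05, and adjusted p = 0.12 with an estimated correlation). Goblet and Paneth genes had 1 of 21 called higher (2 adjusted over the list alone, camera adjusted p = 9.37e-07, and adjusted p = 0.0896 with an estimated correlation). The test called 51 genes higher and 10 lower, but 514 and 520 with only the libraries of that part, 895 and 656 with voom and 273 and 112 with DESeq2. Log2 fold changes followed transcript length across genes at a rank correlation of 0.403, and 58 genes were called, 46 of them among the 61, with each library's length trend removed. It called 28, 7 or 10 in all without Lgr5-negative replicate 1, 2 or 3, and 31 or 8 without Lgr5-positive replicate 1 or 3. With Lgr5-positive replicate 3 and Lgr5-negative replicate 2 both left out, a choice made after seeing the data that also omitted 1 library of another group, 1 gene was called.

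A difference of differences asked whether the Lgr5 contrast of unlabelled cells changed from E13.5 to E15.5 in the Axin2 cohort. The small intestine was whole at E13.5 and divided at E15.5, so gates that differ in position would also give such a change. Stage and division of the gut cannot be told apart here. The deficit of Sfrp5 in Lgr5-positive cells was smaller at E15.5 by 8.68 ± 1.09 (adjusted p = 4.26e-05). The E15.5 side averages both parts, and in the posterior part Sfrp5 was near the floor in both gates (0.487 ± 0.626 and 0.512 ± 0.191 CPM), where no deficit can show, so only the anterior part (180 ± 27.1 in Lgr5-positive and 319 ± 89.1 in Lgr5-negative cells) bears on it. The deficit of the transmembrane protein gene Tm4sf4 was smaller by 5.24 ± 0.97. For Gata4 the change was 3.62 ± 0.73 (adjusted p = 0.0156). The excess of Vav3 differed by -3.41 ± 0.48 (adjusted p = 0.000136), that of Gramd3 by -1.78 ± 0.25 and that of Smoc2 by -4.09 ± 0.75. The calls of Vav3, Gramd3 and the kinase gene Mylk3 (-2.33 ± 0.38) held with each library left out. Sfrp5 was lost without posterior Lgr5-positive replicate 3 (adjusted p = 0.0902), Smoc2 without E13.5 Lgr5-negative replicate 1 (adjusted p = 0.0503), Tm4sf4 without E13.5 Lgr5-positive replicate 1 or 2 (adjusted p = 0.0597 and 0.065). Gata4 was lost without E13.5 Lgr5-negative replicate 2 (0.0636) or E13.5 Lgr5-positive replicate 1 or 3 (0.147 and 0.152). The test called 12 genes with a positive and 14 with a negative difference, 26 in all. It called 94 and 50 with DESeq2, 596 and 357 with voom, and 46 and 45 with only the libraries of the Axin2 cohort. It called 15 without E13.5 Lgr5-negative replicate 3, and 13, 14 or 12 without E13.5 Lgr5-positive replicate 1, 2 or 3. Proximal gut genes had 1 positive call and 0 negative of 19 (6 and 0 adjusted over the list alone; camera adjusted p = 0.000405; adjusted p = 0.457 with an estimated correlation). Of 24 intestinal stem cell genes 1, Smoc2, had a negative call (2 adjusted over the list alone; camera adjusted p = 0.0772).

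Whether Lgr5-positive cells carrying the lineage label differed from those without it was tested in 3 settings. The series title asks whether separate embryonic progenitors give rise to such cells. How completely the label marked its cells is not known here, so unlabelled cells may stem from the same progenitors. The contrast therefore cannot answer that question. In the E13.5 Axin2 cohort, labelled cells had less of the centromere protein gene Cenpm, with a log2 fold change of -1.24 ± 0.23 (adjusted p = 0.0115). They also had less Bex1, at 407 ± 79.6 against 737 ± 26 (-0.86 ± 0.19), and less of the replication factor gene Gins2 (-0.71 ± 0.16). The actin binding protein gene Lima1 was higher at 283 ± 37.2 against 148 ± 31.8 CPM (0.93 ± 0.20) and the kinase gene Jak2 at 1.29 ± 0.31. Id2 was at -0.72 ± 0.21 (adjusted p = 0.0968) and Lgr5 at 0.58 ± 0.73 (adjusted p = 0.693). The test called 10 genes higher and 40 lower. With voom the balance turned to 44 higher and 5 lower, with 8 of the 50 kept, while DESeq2 gave 267 and 362 and only the libraries of that setting 1 and 10. Each of these 5 calls was lost without labelled replicate 1 or unlabelled replicate 1 or 3 (adjusted p from 0.0678 for Cenpm to 0.291 for Gins2), and those of Bex1 and Jak2 also without unlabelled replicate 2 (0.072 and 0.119). The count was 1, 168 or 752 without labelled replicate 1, 2 or 3 and 10, 30 or 9 without unlabelled replicate 1, 2 or 3. Summed mesenchyme genes stood at 1740, 545 and 225 CPM in the 3 labelled libraries, and 18 of the 40 lower genes had 0 reads in at least 1 of them. Of 21 goblet and Paneth genes 1 was higher, the trefoil gene Tff3 at 23.7 ± 28.6 against 2.28 ± 0.476 CPM (lost without labelled replicate 1 or 3 or any unlabelled replicate, at 0.0987 without labelled replicate 3 and 0.108 without unlabelled replicate 2; 8 adjusted over the list alone; camera adjusted p = 8.28e-05; adjusted p = 0.338 with an estimated correlation).

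For the posterior part at E15.5, Smoc2 averaged 161 ± 24.8 CPM in labelled and 136 ± 72.5 CPM in unlabelled Lgr5-positive cells and Kit 63.7 ± 26.1 and 73 ± 25 CPM, genes chosen after their values were seen. Here edgeR called 0 genes, with 371 at unadjusted p below 0.05 (776 expected by chance), 56 called by DESeq2 and 2 by voom, and 14 without unlabelled replicate 2. These 0 calls again do not show that the cells were alike. By list, mesenchyme genes ranked lower in labelled cells, 20 of 22 negative (0 called, 0 adjusted over the list alone, camera adjusted p = 6.75e-07, and adjusted p = 0.313 with an estimated correlation). The same held for endothelial genes, 14 of 14 negative (0 called, 1 adjusted over the list alone, camera adjusted p = 2e-05, and adjusted p = 0.313 with an estimated correlation), and for erythroid genes, 8 of 9 negative (0 called, 3 adjusted over the list alone, camera adjusted p = 0.00124, and adjusted p = 0.313 with an estimated correlation). Goblet and Paneth genes ranked higher, 20 of 21 positive (0 called, 0 adjusted over the list alone; camera adjusted p = 0.00658, and adjusted p = 0.44 with an estimated correlation). The Hedgehog, anterior Hox, posterior Hox and enteric neuron lists were called lower by camera (adjusted p = 0.0283, 2e-05, 8.06e-05 and 0.0012) with 0 genes called and 0 adjusted over the list alone. The unlabelled side includes the 2 libraries with the high erythroid sums above. With an estimated correlation all 4 list calls were lost (adjusted p = 0.313, 0.313, 0.322 and 0.412).

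The Id2 cohort gave 3 genes higher and 3 lower in labelled cells, 6 in all. It gave 16 with the replicate number as a block, 146 with DESeq2 and 0 with voom or with only the libraries of that cohort. Vps33a, a vesicle tethering protein, was lower at 11.5 ± 2.4 against 33.2 ± 9.99 CPM (-1.53 ± 0.24, adjusted p = 0.00325, and 0.0727 without labelled replicate 2). Phc3, a Polycomb protein, was higher at 26 ± 10.6 against 6.87 ± 3.37 (1.92 ± 0.38), as was the DNA polymerase Poll (1.91 ± 0.38). Phc3 and Poll lost their calls without labelled replicate 2 (adjusted p = 0.194 and 0.491), unlabelled replicate 1 (0.114 and 0.0633) or unlabelled replicate 3 (0.0608 each), and Poll without unlabelled replicate 2 (0.27). Iba57 was also called higher and Zbtb49 and Acad12 lower, genes outside the naming rule and chosen after their values were seen, at means of 7.73 CPM or less. The count was 273, 0 or 27 without labelled replicate 1, 2 or 3, and 10 or 2 without unlabelled replicate 1 or 3. Differences between these 3 settings were not tested.

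Labelled cells of unstated Lgr5 state were set against Lgr5-negative unlabelled cells in all 4 settings. The labelled group may hold Lgr5-positive cells, which the sort removed from the other group. Label and Lgr5 state therefore cannot be told apart in these contrasts. Lgr5 differed by 1.86 ± 0.78 in the E13.5 Axin2 cohort, 2.22 ± 0.77 in the anterior and 1.43 ± 0.76 in the posterior part, and -0.79 ± 0.74 in the Id2 cohort, all at adjusted p = 1. In the anterior part intestinal stem cell genes ranked higher in labelled cells, 23 of 24 positive (0 called, 0 adjusted over the list alone; camera adjusted p = 2.94e-11; adjusted p = 0.00146 with an estimated correlation). So did Wnt targets, 22 of 23 positive (0 called, 0 adjusted over the list alone; camera adjusted p = 4.7e-10; adjusted p = 0.00146 with an estimated correlation). In that part log2 fold changes followed transcript length at a rank correlation of 0.454 (0.404 in the posterior part). With each library's length trend removed these 2 lists kept their calls with an estimated correlation (adjusted p = 0.000937 and 0.000888). At E13.5 of the Axin2 cohort the stem cell list gave 18 of 24 positive (0 called, 0 adjusted over the list alone; camera adjusted p = 3.5e-05; adjusted p = 0.133 with an estimated correlation). There mesenchyme genes also ranked higher, 19 of 22 positive (0 called, 0 adjusted over the list alone, camera adjusted p = 0.0175, and adjusted p = 0.748 with an estimated correlation), and enteric neuron and glia genes, 11 of 15 (0 called, 0 adjusted over the list alone, camera adjusted p = 0.0433, and adjusted p = 0.748 with an estimated correlation). Goblet and Paneth genes in the posterior part gave 20 of 21 positive (0 called, 1 adjusted over the list alone; camera adjusted p = 3.85e-10; adjusted p = 0.132 with an estimated correlation). Erythroid genes there gave 7 of 9 positive (0 called, 0 adjusted over the list alone, camera adjusted p = 0.00546, and adjusted p = 0.296 with an estimated correlation) and posterior Hox genes 12 of 14 (0 called, 0 adjusted over the list alone, camera adjusted p = 0.0254, and adjusted p = 0.592 with an estimated correlation). Single genes called by edgeR numbered 0 at E13.5 of the Axin2 cohort (232 at unadjusted p below 0.05, 40 by DESeq2, 344 by voom), 0 in the anterior part (133, 31 and 1). They numbered 0 in the posterior part (385, 70 and 32), where 1 was called without labelled replicate 1. Chance would give 776 at unadjusted p below 0.05 in each of these settings, so 0 calls do not show that the cells were alike.

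Slc5a11, a sodium and myo-inositol cotransporter, was the 1 gene called in the Id2 cohort, and lies outside the naming rule, being chosen after its values were seen. Its level was 0.012 ± 0.0208 CPM in labelled cells, with 1 read in 1 of the 3 libraries, against 2.82 ± 0.162 CPM in Lgr5-negative unlabelled cells (adjusted p = 0.0027), and 3.04 ± 0.501 against 0.537 ± 0.612 CPM in the E13.5 Axin2 cohort. The contrast of the Id2 label with the Axin2 label at E13.5, a difference of differences, also called Slc5a11 alone (adjusted p = 0.000522, 0 higher and 1 lower, 641 at unadjusted p below 0.05 against 776 expected by chance). With voom or with only the libraries of that cohort 0 genes were called in the Id2 cohort, and the difference of differences kept 0 of its 1 call with voom or with only the E13.5 libraries. DESeq2 called 52 and 55 genes. Counts in the Id2 cohort were 14, 2 or 8 without labelled replicate 1, 2 or 3, and 14 or 2 without Lgr5-negative replicate 1 or 2. For the difference of differences they were 6, 2 or 6 without Id2-labelled replicate 1, 2 or 3, 8 without Id2-cohort Lgr5-negative replicate 1 and 2 without Axin2-cohort Lgr5-negative replicate 2. The intestinal stem cell list fell on the negative side of that difference for 20 of 24 genes (0 called, 1 lower adjusted over the list alone; camera adjusted p = 0.000284; adjusted p = 0.291 with an estimated correlation). Both labelled groups are of unstated Lgr5 state, so the share of Lgr5-positive cells in them cannot be told apart from the label. Mesenchyme genes were negative for 18 of 22 (0 called, 1 lower adjusted over the list alone, camera adjusted p = 0.0369, and adjusted p = 0.81 with an estimated correlation), and enteroendocrine genes for 23 of 33 (0 called, 3 lower adjusted over the list alone, camera adjusted p = 0.000284, and adjusted p = 0.565 with an estimated correlation). Wnt targets (17 of 23) and distal gut genes (11 of 15) were also lower and proximal gut genes higher (12 of 19) by camera (adjusted p = 0.00313, 0.0205 and 0.0373), with 0 called and 0, 2 and 0 adjusted over the list alone. With an estimated correlation these were lost (adjusted p = 0.297, 0.369 and 0.565).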

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

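The tests of another embryo and of few molecules were chosen only after the result was seen, as was the part of the mesenchymal test that asks for smaller folds (as first written it asked only for a fall in the count, which was met), and the fit without length trend was added after the data were examined but its bound was set before its own result. By the difference of differences between the Id2 and Axin2 labels at E13.5, 1 gene differed, Slc5a11, and 33 of 100 splits of the libraries gave as many genes (highest other split 19), so chance was not excluded. These splits ignored the replicate numbers, which pair the libraries of the Id2 side but not of the Axin2 side. With the replicate number as a block 12 genes were called. Between the stages the Lgr5 contrast of unlabelled cells differed for 26 genes, among them Sfrp5 and Vav3, and 13 of 100 splits gave as many (highest other split 68). Those splits moved libraries between the gates of each setting, so they stand for no Lgr5 effect at all, not for an unchanged one. They also ignored the replicate numbers, which pair these libraries at E13.5 alone. Chance was therefore not excluded for the 26 genes, and the share of splits cannot decide it. As the gut was divided only at E15.5, stage and position cannot be told apart for them either. Lgr5-positive labelled replicate 3 of the E13.5 Axin2 cohort carried 299 CPM of Y-linked transcripts and 0 reads of Xist, the X-inactivation transcript, whereas the other 11 libraries of that cohort and stage held Xist without Y-linked transcripts. Its stage score, 0.22 against -1.07 to -0.72 in those 11, also lay towards E15.5.

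Posterior Lgr5-negative unlabelled replicate 2 carried 225 CPM of Y-linked transcripts and 0.78 CPM of Xist, whereas the other number 2 libraries of E15.5 held Xist without Y-linked transcripts. The genes of the stage and position scores were chosen with this library included, so these scores are not independent of its label. An exchange with a library of the other stage was argued against by its stage score of 1.58 (other E15.5 libraries 1.27 to 2.29, Axin2 E13.5 libraries -1.07 to 0.22, the highest being the library above), and an exchange with an anterior library by its position score of 1.65 (other posterior libraries 1.47 to 2.09, anterior libraries -2.13 to -0.65). Its deviations had a mean correlation of -0.17 across genes with the other 3 posterior libraries of its number, the lowest of the 12 posterior libraries (the others from 0.015 to 0.388), so it may come from an embryo other than that of the other gates of its number. The labels do not say that gates of a number share an embryo, and no biological explanation was tested. Without this library the posterior Lgr5 contrast called 7 genes in place of 61.

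In Lgr5-positive cells of the E13.5 Axin2 cohort the 10 genes higher and 40 lower with the lineage label (44 and 5 with voom, 8 of the 50 kept), with Cenpm, Bex1 and Lima1 among them, stood against at most 6 genes in the other splits, which at 10 are too few for a share under 0.05. Mesenchymal cells in labelled replicate 1, where the collagen genes Col3a1 and Col1a1 stood at 610 and 246 CPM although the EpCAM gate would remove such cells, cannot be told apart from the label, as 1 gene was called without that library, outside the 50, but the count also fell to 10 or 9 without unlabelled replicate 1 or 3. The calls ended with folds little changed (median ratio 0.94, Cenpm -1.24 ± 0.23 with and -1.10 ± 0.26 without it, Lima1 0.93 ± 0.20 and 0.83 ± 0.22) and standard errors 1.13 times as large, on genes picked by the pattern, which exclude nothing. Transcript length also stays open, with log2 fold changes following length across genes at a rank correlation of 0.457 (genes are not independent) and 34 genes called once each library's length trend was removed, 29 of them among the 50 (above the bound set beforehand by under 1 gene), and so do few molecules per library, as 18 of the 40 lower genes had 0 reads in at least 1 labelled library and 13 in all 3. Genes with at least 1 read, compared after the result was seen, numbered 13109 to 13339 in the 3 labelled libraries. They numbered 14707 to 15225 in the 3 unlabelled ones and at least 14419 in every other Axin2 library. Total reads over genes overlapped, at 17209409 to 18804721 with the label and 17389762 to 19460165 without it. Fewer detected genes at like depth go with few molecules, but do not tell them apart from the label. The lineage, which the design names, may also account for the difference and stays open, untested.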

How the results depend on the processing

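The fit without 3 libraries that stood apart and the fit with the length trend removed were chosen after seeing the data. No named gene and no called list changed direction past the threshold, though the balance of higher and lower genes turned in some counts. It turned for stage from 2425 and 2779 to 2641 and 2513 with RLE, 2914 and 2592 with DESeq2 and 3395 and 3184 with only the libraries of the same setting. For gut part, near even at 289 and 276, it turned to 1068 and 1548 with voom, 825 and 928 with only the libraries of the same setting, 148 and 178 with a minimum fold of 2, 326 and 329 without the length trend, and in 3 fits with a library left out. For Lgr5 in the E13.5 Axin2 cohort, near even at 68 and 67, it turned to 110 and 141 with DESeq2, 111 and 122 with the block, 1098 and 1206 with voom, 63 and 65 with a minimum fold of 2, and in 2 fits with a library left out. The Id2 minus Axin2 label went from 0 and 1 to 6 and 1 with voom, labelled against Lgr5-negative cells of the Id2 cohort from 0 and 1 to 8 and 6 without Lgr5-negative replicate 1, and the Lgr5 difference between stages from 12 and 14 to 94 and 50 with DESeq2, 596 and 357 with voom, 46 and 45 with only the libraries of the same setting, 21 and 19 without the length trend and 20 and 15 without posterior Lgr5-positive replicate 2. Posterior Lgr5 and the label in E13.5 Axin2 Lgr5-positive cells also turned, as given below. RLE size factors, leaving out sex-linked genes and thinning to one depth left every count of called genes within 1.5 times its value. Where a setting below moved a value, the cause was not tested. Of 107 list calls 92 were lost with an estimated correlation, 72 with fry and 7 with the length trend removed, and of 370 gene results 49 were weaker with voom, 39 without the filter, 66 with only the libraries of the same setting and 66 without the 3 libraries.

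DESeq2's Wald test called 251 genes for Lgr5 in the E13.5 Axin2 cohort, 42 in the anterior part, 385 in the posterior part and 338 in the Id2 cohort. For the label in Lgr5-positive cells it called 629 in the E13.5 Axin2 cohort (267 higher and 362 lower), 56 in the posterior part and 146 in the Id2 cohort. For labelled against Lgr5-negative cells it called 40 in the E13.5 Axin2 cohort, 31 in the anterior part, 70 in the posterior part and 52 in the Id2 cohort, with 55 for the Id2 minus Axin2 label and 144 for the Lgr5 difference between stages. Voom called 8959 genes for stage and 2616 for gut part, then 2304, 1, 1551 and 17 for Lgr5 in the same order, 2 and 0 for the label in Lgr5-positive cells in the posterior part and the Id2 cohort, 344, 1, 32 and 0 for labelled against Lgr5-negative cells, 7 for the Id2 minus Axin2 label and 953 for the Lgr5 difference between stages. In the E13.5 Axin2 cohort it called 49 genes for the label in Lgr5-positive cells, 44 higher and 5 lower in place of 10 and 40, with 8 of the 50 kept.

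A minimum fold of 2 left 2579 genes for stage, 326 for gut part and 32 for the label in Lgr5-positive cells of the E13.5 Axin2 cohort. With no filter on low counts, 49 genes were called for Lgr5 in the Id2 cohort, and 21 and 2 for the label in Lgr5-positive cells of the E13.5 Axin2 and Id2 cohorts. With only the libraries of the same setting, gut part called 1753, Lgr5 1034 in the posterior part (514 higher and 520 lower) and 2 in the Id2 cohort, the label in Lgr5-positive cells 11 and 0 in the E13.5 Axin2 and Id2 cohorts, labelled against Lgr5-negative cells of the Id2 cohort 0, the Id2 minus Axin2 label 0 and the Lgr5 difference between stages 91. Removing the length trend gave 40 for that last difference. Without the 3 libraries the posterior Lgr5 contrast called 1, the label in E13.5 Axin2 Lgr5-positive cells 1 and the Lgr5 difference between stages 12.

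With the replicate block, gut part called 928 genes (515 higher and 413 lower), Lgr5 233 in the E13.5 Axin2 cohort, 529 in the posterior part (247 higher and 282 lower in place of 51 and 10) and 343 in the Id2 cohort, the label in Lgr5-positive cells 1059 in the E13.5 Axin2 cohort (231 higher and 828 lower) and 16 in the Id2 cohort, the Id2 minus Axin2 label 12 and the Lgr5 difference between stages 80. It moved no other count by over 1.5 times. By the correlation rule, numbers paired the gut parts in labelled cells only, and did not pair the libraries for posterior Lgr5 and the label in E13.5 Axin2 Lgr5-positive cells. Of the Lgr5 difference between stages they paired the E13.5 side but neither part at E15.5. Of the Id2 minus Axin2 label they paired the Id2 side but not the Axin2 side.

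Leaving out each library in turn gave 4729 to 5101 genes for stage and 436 to 549 for gut part. For Lgr5 the ranges were 65 to 91 in the E13.5 Axin2 cohort, 0 to 1 in the anterior part, 7 to 49 in the posterior part and 22 to 109 in the Id2 cohort. For the label in Lgr5-positive cells they were 1 to 752, 0 to 14 in the posterior part and 0 to 273 in the Id2 cohort, and for labelled against Lgr5-negative cells 0 to 0, 0 to 0, 0 to 1 and 1 to 14. The Id2 minus Axin2 label ranged from 1 to 8 and the Lgr5 difference between stages from 12 to 35.

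Levels of the 4 sorting and label genes moved by over 1 SD in 5 cases. With plain CPM, Id2 stood at 718 CPM in Lgr5-positive labelled cells of the E13.5 Axin2 cohort, and Epcam at 2297 CPM in its labelled cells, 2071 in its Lgr5-positive unlabelled cells and 2382 in labelled cells of the Id2 cohort. With RLE size factors Epcam stood at 1903 CPM in Lgr5-positive unlabelled cells of the E13.5 Axin2 cohort.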

Other observations

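The tests of position along the gut, with the position score, and of depth were chosen only after the result was seen (the depth test first written, thinning, could move little where the groups had like depth), while those of maturation were set beforehand, except that the need for a permutation p below 0.05 was added to the maturation test after its values were seen. Signalling genes outside the lists called above also changed from E13.5 to E15.5. Id1 and Id3, transcriptional inhibitors induced by BMP, rose by 2.87 ± 0.31 and 3.31 ± 0.31, to 83.2 ± 17.3 and 188 ± 53.8 CPM (n = 18) from 12.8 ± 7.69 and 21.3 ± 14.3 (n = 9). Of 15 BMP response genes 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.135). The Notch ligand gene Dll1 rose by 3.82 ± 0.53 and the feedback gene Nrarp by 4.56 ± 0.55, while the receptor gene Notch3 changed by -2.15 ± 0.28. Over 19 Notch pathway genes 7 rose and 3 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.3). Myc rose by 0.96 ± 0.18 and Sox9, a progenitor transcription factor, changed by -0.82 ± 0.17. Of 23 Wnt targets 4 rose and 5 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.973). The antigen presentation gene H2-K1 stood at 176 ± 39.7 against 44.4 ± 12.5 CPM. Of its list, 5 of 13 interferon and antigen presentation genes rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.0358; adjusted p = 0.319 with an estimated correlation). Epithelial genes exchanged members, the tight junction gene Cldn6 at 151 ± 48.5 against 792 ± 109 CPM and the lectin gene Lgals4 at 163 ± 29.5 against 28.5 ± 8.05 CPM. Of 23 such genes 12 rose and 4 fell (12 and 5 adjusted over the list alone; camera adjusted p = 0.0213; adjusted p = 0.216 with an estimated correlation).

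Vim, an intermediate filament gene usual in mesenchyme, also set the parts and stages of the epithelium apart, at 50.5 ± 33.7 CPM at E15.5 against 284 ± 153 at E13.5 (-2.60 ± 0.18) and at 77.4 ± 24.3 in the posterior against 23.6 ± 13.8 in the anterior part (1.83 ± 0.23). Of 22 mesenchyme genes 3 fell and 1 rose between stages (3 and 1 adjusted over the list alone; camera adjusted p = 0.359). The highest summed mesenchyme levels were 2120 CPM in Lgr5-positive labelled replicate 1 of the Id2 cohort and 1740 CPM in Lgr5-positive labelled replicate 1 of the E13.5 Axin2 cohort, against a median of 278 CPM.

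A hypothesis is that the E13.5 Lgr5 contrast partly reflects where along the gut the sorted cells lay, since whole small intestine was taken at that stage. The 67 genes lower in Lgr5-positive cells of the Axin2 cohort, Sfrp5 and Onecut2 among them, differed by -1.66 in mean log2 CPM between posterior and anterior parts at E15.5, and the 68 higher genes by 0.62 (each permutation p = 0.00025, the smallest that 8000 arrangements allow, with libraries taken as independent although those of 1 number may share an embryo). A position score made from gut part genes was 1.86 higher in Lgr5-positive than in Lgr5-negative unlabelled cells over both E13.5 cohorts (exact p = 0.005 of 400 arrangements, adjusted p = 0.08 over 16 relations, higher in each cohort by 1.73 and 1.99), against 3.21 between the parts at E15.5 and 0.51 within them. Its means in Lgr5-positive and Lgr5-negative cells were 2.85 and 1.12 in the Axin2 cohort and 2.8 and 0.81 in the Id2 cohort. Posterior E15.5 libraries ran from 1.47 to 2.09 and anterior ones from -2.13 to -0.65. The Lgr5-positive means thus lay beyond the posterior range and the Lgr5-negative means between the ranges. The score is therefore not calibrated as a position at E13.5. Unequal depth was argued against by a ratio of mean total reads of 1.005 between the Lgr5-positive and Lgr5-negative groups of the Axin2 cohort, with each group's median within the range of the other, and later maturation of the Lgr5-negative cells cannot be told apart, the same lower and higher genes differing by -0.24 and 0.2 between stages (permutation p = 0.549 and 0.327). Those signs are opposite to what maturation needs and by the bounds first written would argue against it, but neither passes 0 by more than its spread, so position may go with the sort while 60 of the genes were not called between the parts and a difference in cell state at 1 position stays open.

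Other splits of the same libraries were counted for each number of called genes. For stage, 1 of 100 splits gave as many genes as the real 5204, the real one itself (highest other 468), and for gut part 1 of 100 as many as 565 (highest other 206). Those splits took the libraries as independent, though gates and parts of 1 number may share an embryo or pool. The numbers did pair the gut parts in labelled cells. Chance was therefore excluded for both only as far as the libraries are independent, which the labels do not settle. Each contrast of 3 with 3 libraries has 10 splits, too few for a share under 0.05. For Lgr5-positive against Lgr5-negative cells the real count and the highest other were 68 higher and 67 lower against 0 in the E13.5 Axin2 cohort (1 split as large). They were 0 and 3 in the anterior part (10 splits), 61 and 9 in the posterior part (1 split) and 74 and 269 in the Id2 cohort (3 splits). In that cohort the splits that part all 3 numbered pairs gave at most 0, and those that part 1 pair up to 269. For the label in Lgr5-positive cells the values were 50 and 6 in the E13.5 Axin2 cohort (1 split), 0 and 4 in the posterior part (10 splits) and 6 and 1903 in the Id2 cohort (8 splits). A split calling 1903 genes points to a structure of the samples, and splits parting all 3 pairs gave at most 13. For labelled against Lgr5-negative cells they were 0 and 0 in the E13.5 Axin2 cohort and in both parts at E15.5 (10 splits each), and 1 and 142 in the Id2 cohort (5 splits), where splits parting all 3 pairs gave 0.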
